A study of Python regius with 6 samples.

How the data were processed

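RNA-seq was carried out on ventricle from 6 ball pythons (Python regius), 3 of them fasted and 3 fed. Per the labels' protocols, total RNA was extracted with Tri Reagent and chloroform, and 1 µg of it entered a KAPA HyperPrep mRNA library for each animal. The libraries were read on a NextSeq from 1 end only, with a read length of 76 bases. Per the submitters' processing notes, the authors used FastQC, HISAT2, SAMtools, featureCounts from Subread 1.6.2, and DESeq2 1.26.0. The order and settings of these steps, the genome build and the annotation are not given in the sources used here.

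The authors deposited 1 table with 35366 rows, each with its own RefSeq transcript identifier. Of these identifiers, 32702 have the prefix of a predicted messenger RNA model and 2664 that of a predicted non-coding RNA model. The table pairs no identifier with a gene symbol, and no gene annotation was used here. Its 6 columns of values are headed by alignment file names. None of the 6 headings matches the title, description or characteristics of any sample. Assigning them by their order would have been a guess about which animals were fed, so these 6 columns were not used here. Depth per library and expression levels were therefore not analysed here. The comparison of transcripts between fed and fasted hearts, the tests of gene lists and the principal components were planned before the data were examined and were not run. No gene is named for the same reason.

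The values analysed are the tissue mass in mg and the RNA concentration in ng/µl that the submitters recorded for each sample. Groups were taken from the sample titles. RNA concentration was divided by tissue mass for each sample. Group means were compared with an exact two-sided permutation test over all 20 splits of the 6 samples into groups of 3, so the smallest p it can give is 0.1. The threshold was 0.05, which this design cannot reach. Alternatives were RNA concentration without division by mass, leaving out each sample in turn, and a replicate block. The block, and leaving samples out of the comparisons of mass and of concentration alone, were chosen after seeing the data. Each animal was sampled in 1 state, so equal replicate numbers in the groups do not mark the same animal. Computations used Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1.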

Results

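The series addressed how the python heart changes its gene expression after a meal. Ball pythons went through repeated feeding cycles of 28 days before the experiment. The 3 fasted animals were sampled at the end of a 28-day fast. The 3 fed animals were sampled 24 h after a meal of rats of about 25% of body mass that ended such a fast. RNA was measured in the ventricle, the pumping chamber of the heart. The columns of the deposited expression table do not carry names that tie them to these animals, so gene expression in fed and fasted hearts was not analysed here. The measurements that are tied to each animal are the tissue mass and the RNA concentration of its extract.

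Mean RNA concentration per mg of ventricle was lower in fed than in fasted pythons, but by less than the SD of the fed animals. It was 10.0 ± 0.621 ng/µl per mg in the fasted ventricles (SD, n = 3) and 9.18 ± 1.17 ng/µl per mg in the fed ventricles (SD, n = 3). The difference of means, fed minus fasted, was -0.867 ng/µl per mg (exact two-sided permutation test, p = 0.3). The smallest p that 3 animals against 3 can give is 0.1, so the test could not have passed a threshold of 0.05. The fasted ventricles gave 9.33, 10.3 and 10.5 ng/µl per mg in replicates 1, 2 and 3. The fed ventricles gave 9.57, 7.86 and 10.1 ng/µl per mg in replicates 1, 2 and 3. Without fed replicate 2 the difference was -0.211 ng/µl per mg, and without fed replicate 3 it was -1.32 ng/µl per mg. The volume in which the RNA was dissolved is not given in the sources used here, so the ratio is not an RNA yield and compares ventricles only if that volume was equal.

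The RNA extracts of the fed ventricles spanned a wider range of concentrations than those of the fasted ventricles. The concentration was 474 ± 18.3 ng/µl in the fasted group (SD, n = 3), with a range of 455 to 491.5 ng/µl. It was 396 ± 160 ng/µl in the fed group (SD, n = 3), with a range of 268 to 575.2 ng/µl. The means differed by -77.7 ng/µl, fed minus fasted (exact two-sided permutation test, p = 0.4). This difference was -13.5 ng/µl without fed replicate 1, -52.5 ng/µl without fed replicate 2 and -167 ng/µl without fed replicate 3. The masses extracted also spanned a wider range in the fed group, 28 to 57 mg against 44 to 51 mg in the fasted group. Per mg of tissue, the range was 7.86 to 10.1 ng/µl in the fed group and 9.33 to 10.5 ng/µl in the fasted group. None of these differences in spread was tested.

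The recorded tissue masses were 51, 44 and 47 mg in fasted replicates 1, 2 and 3, and 28, 44 and 57 mg in fed replicates 1, 2 and 3. The mean was 47.3 ± 3.51 mg in the fasted group and 43.0 ± 14.5 mg in the fed group (SD, n = 3 each). Fed minus fasted, the difference was -4.33 mg (exact two-sided permutation test, p = 0.8). Its sign depended on 1 sample, since it was 3.17 mg without fed replicate 1. It was -11.3 mg without fed replicate 3 and -2.50 mg without fasted replicate 1. The labels do not say which part of the ventricle was weighed, and these masses are not measurements of heart size.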

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

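The lower mean RNA concentration per mg in fed ventricles, which missed the threshold, kept its direction with each sample left out in turn and for RNA concentration alone. Leaving out each sample in turn gave differences, fed minus fasted, from -1.32 to -0.211 ng/µl per mg, with exact two-sided permutation p from 0.2 to 0.6. Leaving samples out of the other measures was chosen after seeing the data. It moved the difference in tissue mass from -11.3 mg without fed replicate 3 to 3.17 mg, with the sign turned, without fed replicate 1. It moved that in RNA concentration from -167 ng/µl without fed replicate 3 to -13.5 ng/µl without fed replicate 1. The smallest p possible with 5 samples is 0.1. RNA concentration alone differed by -77.7 ng/µl (exact permutation p = 0.4). It is the numerator of the ratio and is not divided by the mass extracted, so the shared sign is not separate support. With a replicate block, chosen after seeing the data, the mean of the paired differences was -0.867 ng/µl per mg (exact sign-flip permutation p = 0.5, where 3 pairs allow 0.25 at the least). That mean equals the unpaired difference by construction, and the animals share only a number. With this few animals, p-values say nothing about stability. The other settings listed beforehand for the transcript and gene list comparisons (pseudocounts, filters, scalings, replicate block, libraries left out, count models and set tests) were not run, since those comparisons were not made.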

Other observations

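The tests in this part were chosen after the values were seen. RNA concentration differed between the 6 samples, from 268 to 575.2 ng/µl, and a candidate explanation is the mass of tissue extracted. Across all 6 samples, concentration rose with tissue mass, with Pearson's r = 0.921 (exact permutation p = 0.0111 over 720 orders) and Spearman's rho = 0.928 (exact permutation p = 0.0167). The 2 samples farthest from the median mass of 45.5 mg were fed replicate 1 at 28 mg and fed replicate 3 at 57 mg. Without them the masses span only 44 to 51 mg, and r was 0.587 over 4 samples (exact permutation p = 0.5, where the smallest possible is 0.0833). The relation therefore stayed positive but was not tested with any power without these 2 samples. Within groups, the deviations of concentration and mass from their group means had r = 0.925 (exact two-sided permutation p = 0.222). That p counts the 8 of the 36 orders within groups whose r was as large in size, with either sign. The 28 and 57 mg samples are both fed, so this r rests mainly on the fed group. In the fasted group, the samples of 44, 47 and 51 mg gave 455, 491.5 and 475.7 ng/µl. The pooled and the within-group Pearson p were adjusted together, with the lower one multiplied by 2. The adjusted exact permutation p was 0.0222 for the pooled relation and 0.222 within groups, where no positive relation could have passed. The p of Spearman's rho and the p over 4 samples were not part of this adjustment. No batch is named in the labels. No biological explanation was tested.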
